A study of Rattus norvegicus with 123 samples.

How the data were processed

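Liver RNA of Wistar rats was measured on Affymetrix RaGene 2.0 ST arrays, 123 in all, after daily gavage with 1 of 8 compounds or a vehicle. Per the labels' protocols, animals were randomised to dose groups and killed the day after the last dose, and all RNA samples passed a check of their integrity. The deposited table holds log2 values for 23110 transcript probe sets on every array, and per the submitters' processing notes they were made with RMA and affy, with no version given. Whether all arrays were normalized in 1 run is not stated. Groups, doses, days and vehicles were taken from the labels, which give doses in mg/kg while the group names say ppm. The letters F and M in the group names of the cyproterone acetate study are not spelled out, and the labels describe male animals throughout, so these groups are called F and M as named.

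The probe sets carry Ensembl transcript identifiers only. The gene table at hand, of assembly GRCr8 with 47357 genes, holds no such identifiers, and 0 probe sets could be paired with a gene symbol. The unit of every test is therefore the transcript, not the gene that had been planned. The 29 gene lists fixed before the data were examined, the named genes by symbol and the mean over the probe sets of a gene could not be run. The rule set for named genes took the largest rises and falls per comparison among those past the threshold whose treated and control arrays do not overlap. It was applied to transcripts, and of those named only the 2 with the largest rise and the 2 with the largest fall over the series are printed by identifier, a limit adopted after the data were examined because no names are available. Of the probe sets, 640 had the same value as an earlier one on every array and were left out, which left 22470. For 2179 of these (9.7%), another probe set had a residual correlation above 0.9, so neighbouring or overlapping transcripts of 1 gene are counted more than once in what follows.

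The labels mark 11 arrays as not of good quality, among them the technical repeat of 1 control animal, and these were left out, leaving 112 arrays. A linear model with 1 mean per group was fitted to all 29 groups with limma 3.58.1 in R 4.3.3, with moderated variances and no trend. It had 83 residual and 4.23 prior degrees of freedom. Each of the 17 treated groups was compared with the control group of the same vehicle, set letter and day, and 11 differences between such comparisons were tested for time, dose, compound and F against M. A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values below are from this fit unless another test is named. Direct comparisons of F with M groups, in controls and in treated animals, were added after the data were examined. The number of arrays limits the precision. Changes of 0.5, 1 and 2 log2 units were simulated among 22470 transcripts, with independent normal noise at each transcript's moderated SD over all groups. At 0.05, 35.7%, 87.7% and 97.5% were recovered for methapyrilene 30 mg/kg at 28 d, with 5 false calls. For Wy-14643 at 28 d the shares were 50.8%, 93% and 100%, with 8 false calls. For a difference between comparisons, cyproterone acetate F minus M at 28 d, they were 14.5%, 78.8% and 95.8%, with 2 false calls. The simulation gave all groups the same spread, so in groups with a wider spread recovery can be lower and false calls more frequent. The arrays of methapyrilene 30 mg/kg at 28 d lay 0.31 to 0.37 from the other arrays of their group, against a median of 0.28 over the 112 arrays.

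In place of the gene lists, 17 sets of transcripts were defined from the data themselves: those raised or lowered by a compound, and those that differ at least 2-fold between the F and M controls of 1 day. Each was tested in comparisons it was not taken from, with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over all 244 tests. They passed the threshold in 193 tests, and in 131 with an estimated correlation. All were chosen after the data were examined, and 7 are described one by one. For comparisons that share control animals, unchanged groups were simulated against the same controls 100 times. Where 5 controls allowed it, they were also split into 2 and 3, each part serving 1 of the comparisons. The same-sign shares and shared calls obtained in these ways were added after the data were examined. Transcripts called in the same direction for at least 4 of the 6 carcinogens at 28 d, and in no direction for either non-carcinogen, were counted as shared, beside 1000 shuffles of the calls. Pioglitazone at 63 mg/kg stood for that compound.

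Every count was recomputed with all 123 arrays, with only the groups of the same control set, with arrays centred on their medians, with quantile normalization, without the dimmest 40% of transcripts, with a trend and robust variances, with replicate numbers as a block, and without each array in turn. Draws of 3 arrays per group, 20 in all, were added after the data were examined, and the median count over the draws is given. Splits of the same arrays into groups of the same sizes were counted, up to 100 per comparison. Figures were drawn with matplotlib 3.10.9.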

Results

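The series asks how the liver transcriptome of rats responds to compounds classed as liver carcinogens, and sets them against 2 compounds classed as non-carcinogens. Phenobarbital at 80 mg/kg was given for 14 d (3 arrays used), 28 d (5) and 90 d (3). Wy-14643 at 60 mg/kg (5) and 1,4-dichlorobenzene at 600 mg/kg (4) were given for 28 d. Cyproterone acetate at 100 mg/kg was given to M and F groups for 14 and 28 d, with 4 arrays in each group. Methapyrilene was given at 30 mg/kg for 14 and 28 d and at 100 mg/kg for 14 d, and piperonyl butoxide at 600 mg/kg for 14 and 28 d, with 3 arrays in each group. The non-carcinogens were pioglitazone at 16 mg/kg (3) and 63 mg/kg (5) and rosiglitazone at 10 mg/kg (3), both for 28 d. The 12 control groups received carboxymethylcellulose, corn oil or water and hold 3 to 5 used arrays each. Median log2 values per array lay between 5.43 and 5.64, and the median residual SD of a transcript within groups was 0.20.

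The number of transcripts changed ranged from 11 to 10809 of the 22470 tested. Methapyrilene at 100 mg/kg changed 48.1% of them and Wy-14643 changed 24.3%, while pioglitazone at 16 mg/kg changed 11 transcripts. The counts are not on equal footing, since groups hold 3 to 5 arrays. With 3 arrays drawn per group, phenobarbital at 14 and 28 d called 136 and 104, 1,4-dichlorobenzene 755, cyproterone acetate in M 1436 and 1643, pioglitazone at 16 and 63 mg/kg 6 and 74 and rosiglitazone 62. Wy-14643 then called 3841 and cyproterone acetate in F 2138.5 and 2523. These are medians of 20 draws, which ran from 66 to 583 for phenobarbital at 14 d and from 8 to 201 for pioglitazone at 63 mg/kg.

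**Figure D1:**
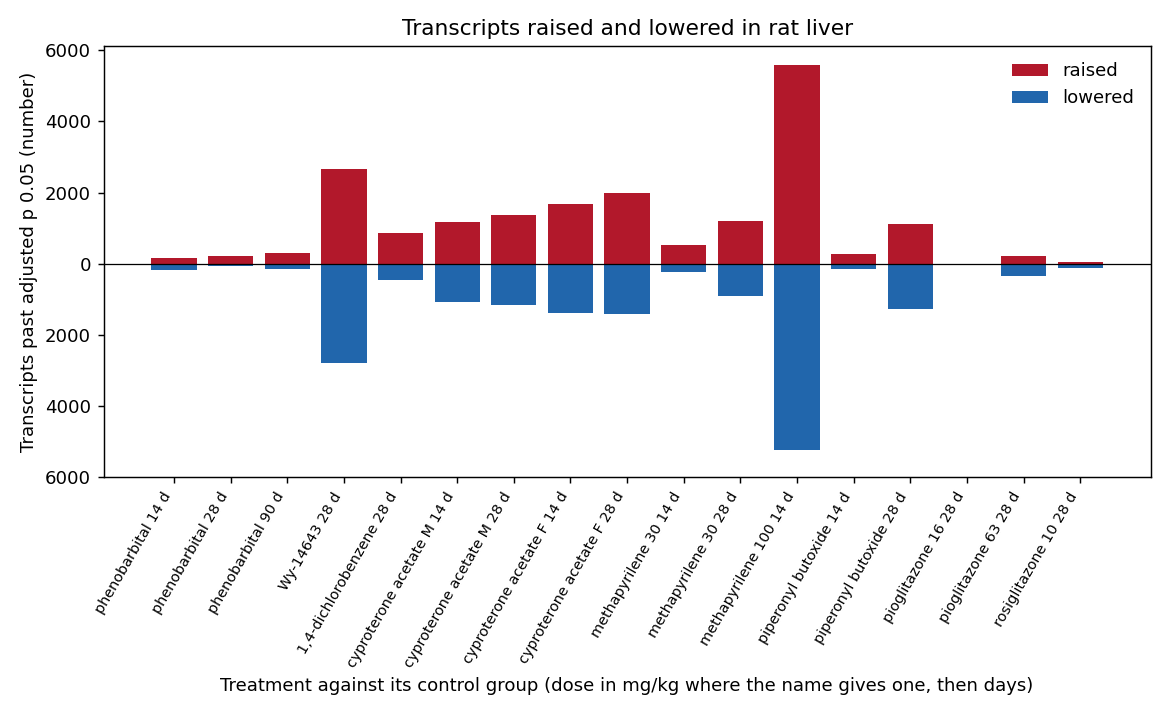
Number of transcripts raised (red, above 0) and lowered (blue, below 0) at an adjusted p under 0.05 in each of the 17 comparisons of a treated group with its control group; the x axis gives compound, dose in mg/kg where the name holds one, and days. The bars run from 5 raised and 6 lowered with pioglitazone at 16 mg/kg to 5582 raised and 5227 lowered with methapyrilene at 100 mg/kg.

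Phenobarbital, a barbiturate known to induce drug-metabolising enzymes in liver, raised a small and recurring group of transcripts. It changed 323 transcripts at 14 d (151 raised, 172 lowered), 277 at 28 d (214 raised, 63 lowered) and 446 at 90 d (306 raised, 140 lowered). Of the 459 raised at any time, 70 were raised at all 3 times, against 4 of the 333 lowered at any time. ENSRNOT00000044127 led the raised transcripts at each time. Its log2 level was 12.47 ± 0.22 (SD, n = 5) at 28 d, against 6.22 ± 1.67 (n = 5) in controls, a rise of 6.25 (SE 0.57, adjusted p = 3.43e-14). The rise was 6.60 (SE 0.66) at 14 d and 7.67 (SE 0.69) at 90 d. Of the transcripts called at 28 d, 95.7% had the same sign at 90 d and 90.3% at 14 d. The difference between times passed the test for 16 transcripts between 28 and 14 d and for 1 between 90 and 28 d, and the median half-width of the 95% interval of those differences was 0.39 and 0.40. These 2 counts were 1 and 0 with only the same control set and 66 and 1 with all arrays. Without 1 array they ran from 3 (without the 14 d control replicate 4) to 69 (without the 14 d control replicate 1) and from 0 to 8 (without the 90 d treated replicate 2). With only the groups of the same control set in the fit, the counts were 85 (62 raised, 23 lowered), 148 and 280. With the arrays not marked as of good quality included they were 1085 at 14 d and 896 at 90 d. With 1 array left out, the 14 d count fell to 181 and 143 without control replicates 3 and 4 and to 141 and 138 without phenobarbital replicates 3 and 5, and the 90 d count fell to 241 without phenobarbital replicate 4.

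The 70 transcripts that phenobarbital raised at all 3 times also rose with most of the other carcinogens. With 1,4-dichlorobenzene, an aromatic chlorinated hydrocarbon, 63 of the 70 rose and 0 fell, with a median log2 change of 0.88 (adjusted p = 6.6e-15 with an estimated correlation). With cyproterone acetate, a steroid with antiandrogenic and progestogenic activity, 53 rose and 0 fell in the M group at 28 d (median 0.65) and 48 rose and 2 fell in the F group (median 0.51). With piperonyl butoxide, an insecticide synergist that inhibits cytochrome P450 enzymes, 33 rose at 14 d and 47 at 28 d (median 0.66), and 0 fell. These shifts passed the test with an estimated correlation. Wy-14643 raised 32 and lowered 13 (median 0.27, adjusted p = 0.158 with an estimated correlation), and methapyrilene at 100 mg/kg raised 29 and lowered 25 (adjusted p = 0.255). Methapyrilene at 30 mg/kg raised 13 and lowered 0 at 14 d (adjusted p = 0.041 with an estimated correlation), and raised 14 and lowered 9 at 28 d (adjusted p = 0.173 with an estimated correlation). Pioglitazone at 63 mg/kg raised 5 and lowered 1 (adjusted p = 0.995). Rosiglitazone raised 0 and lowered 2, with a median of -0.09 (adjusted p = 0.0214, and 0.35 with an estimated correlation). The set was chosen in these animals, but none of the compounds set against it shares phenobarbital's control arrays. How far it differs between compounds was not tested.

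**Figure D2:**
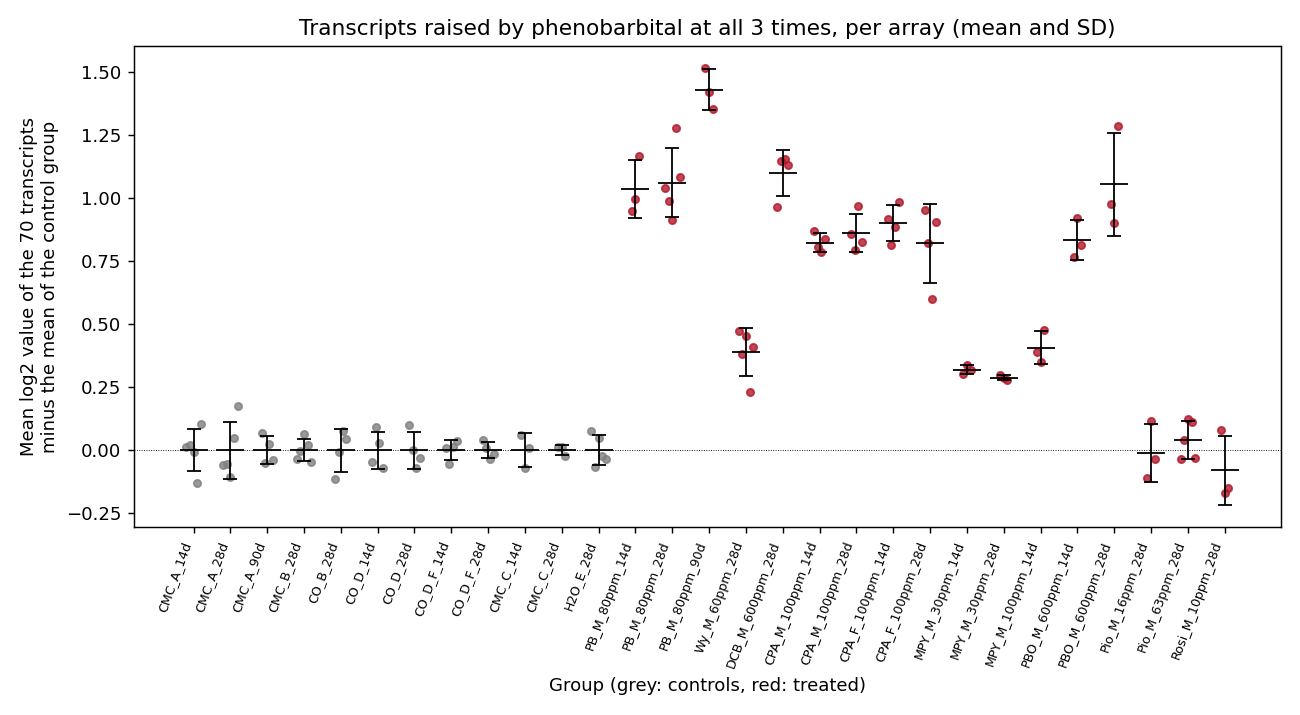
Mean log2 value of the 70 transcripts raised by phenobarbital at 14, 28 and 90 d, on each used array, minus the mean of its control group (y axis), by group (x axis); grey points are control arrays, red points treated arrays, and bars the group mean and SD. Phenobarbital groups average 1.04, 1.06 and 1.43, for which the set was chosen, 1,4-dichlorobenzene averages 1.10, Wy-14643 0.39 and rosiglitazone -0.08.

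ENSRNOT00000044127, the transcript that led the phenobarbital response, rose with every carcinogen at 28 d. The log2 rise was 7.84 (SE 0.74) with piperonyl butoxide, 6.29 (SE 0.64) with 1,4-dichlorobenzene, 5.44 (SE 0.57) with Wy-14643, 4.06 (SE 0.64) and 2.60 (SE 0.64) with cyproterone acetate in the F and M groups, and 2.55 (SE 0.74) with methapyrilene at 30 mg/kg. Its differences were 0.17 (SE 0.66), 0.45 (SE 0.57) and 0.45 (SE 0.66) with pioglitazone at 16 and 63 mg/kg and with rosiglitazone, with adjusted p of 0.974, 0.759 and 0.885. In the 28 d controls it was lower in the F than in the M group, with a difference of -2.65 (SE 0.64, adjusted p = 0.00234).

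**Figure D3:**
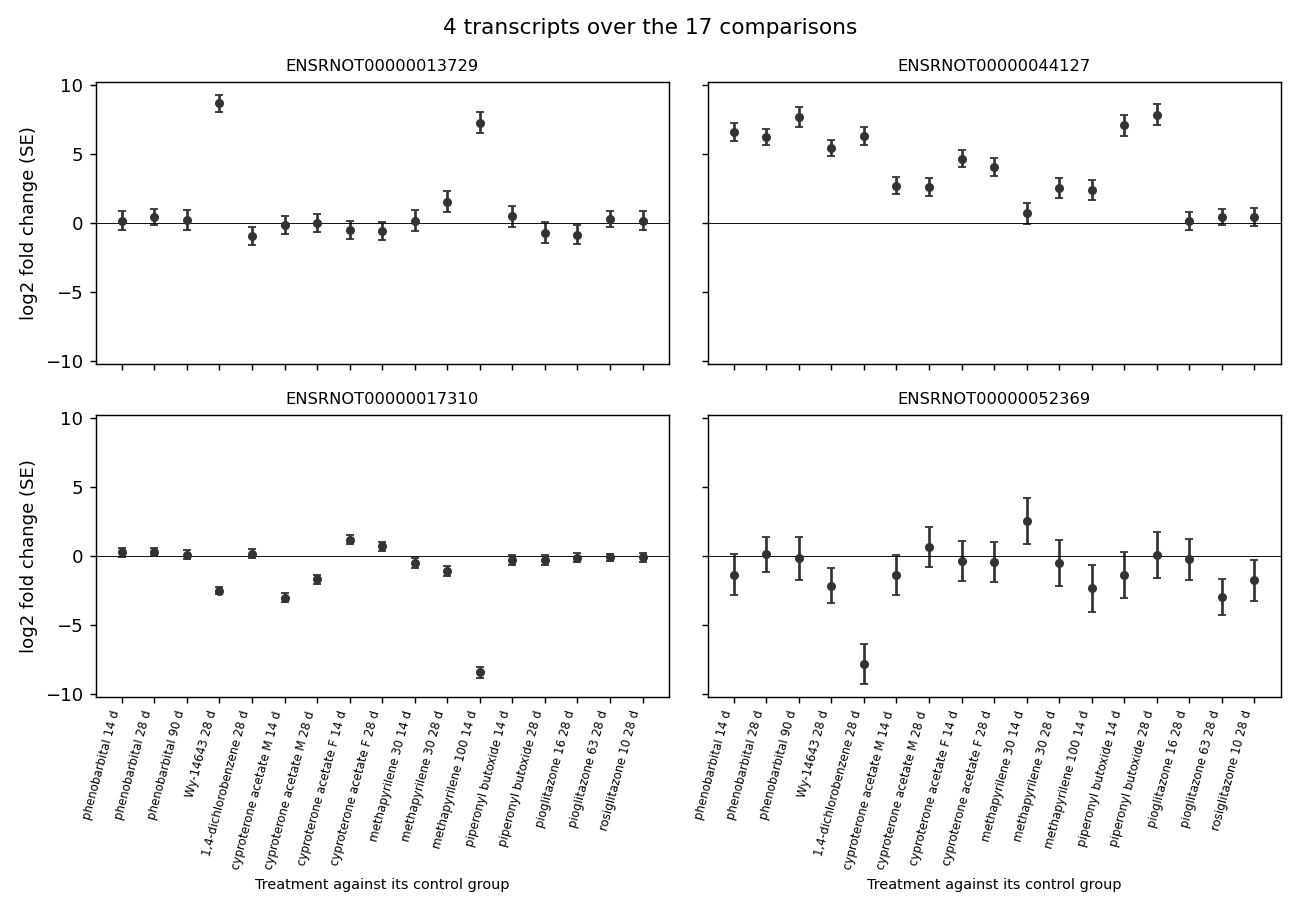
Log2 fold change (y axis, with the standard error) of 4 transcripts in the 17 comparisons of treated with control groups (x axis: compound, dose in mg/kg where the name holds one, days). ENSRNOT00000044127 rose by 6.25 to 7.67 with phenobarbital, ENSRNOT00000013729 by 8.67 with Wy-14643 and 7.26 with methapyrilene at 100 mg/kg, ENSRNOT00000017310 changed by -8.44 with methapyrilene at 100 mg/kg and ENSRNOT00000052369 by -7.82 with 1,4-dichlorobenzene.

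Wy-14643, an agonist of the nuclear receptor PPAR alpha and a peroxisome proliferator in rats, changed 5466 transcripts, of which 2668 rose and 2798 fell. At least 2-fold changes made up 344 rises and 269 falls. ENSRNOT00000013729 rose from 2.43 ± 1.09 (SD, n = 5) to 11.10 ± 0.65 (n = 5), a log2 change of 8.67 (SE 0.59, adjusted p = 1.03e-22). The only other comparison in which this transcript passed the test was methapyrilene at 100 mg/kg, where it rose by 7.26 (SE 0.77, adjusted p = 8.73e-14). The transcripts that Wy-14643 lowered at least 2-fold fell with many of the other compounds, a non-carcinogen included: 195 of 269 with methapyrilene at 100 mg/kg (median -1.32), 121 with piperonyl butoxide at 28 d (median -0.51), 101 with methapyrilene at 30 mg/kg at 28 d (median -0.47) and 99 with cyproterone acetate in the M group at 28 d (median -0.36). Pioglitazone at 63 mg/kg lowered 24 and raised 0 (median -0.12, adjusted p = 0.00817 with an estimated correlation). All 5 shifts passed the test with an estimated correlation. That test was not passed for cyproterone acetate in the F group at 14 d, with 86 lowered and 40 raised (adjusted p = 0.000103, and 0.0758 with an estimated correlation), for phenobarbital at 14 d, with 12 and 4 (7.77e-05 and 0.0703), or for rosiglitazone, with 6 and 0 (0.000114 and 0.0777). Pioglitazone at 16 mg/kg changed 0 of them (adjusted p = 0.0604, and 0.405 with an estimated correlation). Of the 344 that it raised at least 2-fold, 184 rose with methapyrilene at 100 mg/kg and 37 fell (adjusted p = 0.0178 with an estimated correlation). The same 344 split into 59 rises and 28 falls with cyproterone acetate in the M group at 28 d (adjusted p = 0.217).

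1,4-Dichlorobenzene changed 1340 transcripts, with 874 raised and 466 lowered, and 755 with 3 arrays drawn per group. Its largest fall was that of ENSRNOT00000052369, from 9.50 ± 0.38 (SD, n = 4) to 1.68 ± 0.55 (n = 4), a log2 change of -7.82 (SE 1.45, adjusted p = 7.13e-05). Values of this transcript fall into separate clusters over the series, 23 arrays between 1.32 and 5.33 and 100 arrays between 7.26 and 10.44, and 3 of 53 control arrays lie in the lower cluster.

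Methapyrilene, an antihistamine that damages rat liver, had its widest effect at 100 mg/kg. At 30 mg/kg it changed 760 transcripts at 14 d (519 raised, 241 lowered) and 2120 at 28 d (1207 raised, 913 lowered). At 100 mg/kg and 14 d it changed 10809 (5582 raised, 5227 lowered), 2688 of them at least 2-fold. ENSRNOT00000017310 fell from 12.53 ± 0.08 (SD, n = 3) to 4.08 ± 1.13 (n = 3) at 100 mg/kg, a log2 change of -8.44 (SE 0.37, adjusted p = 1.78e-36). At 30 mg/kg and 28 d the change was -1.11 (SE 0.37, adjusted p = 0.0394). The doses differed at 14 d in 8157 transcripts. Of the 2120 transcripts called at 30 mg/kg at 28 d, whose control animals were others, 95.5% had the same sign at 100 mg/kg at 14 d and 1782 were called in the same direction. Their median change in the direction of the call was 0.56 at 30 mg/kg and 1.03 at 100 mg/kg. Between 28 and 14 d at 30 mg/kg, limma called 0 transcripts, with 1020 at an unadjusted p under 0.05 and a median half-width of the 95% interval of 0.47.

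The direction of the methapyrilene calls moved with the scaling between arrays. With arrays centred on their medians, which shifted the median of all transcripts by -0.14, 35.8% of the calls at 100 mg/kg were rises, against 51.6%. For the difference between doses (shift -0.11) the share was 40.1%, against 57.4%, and at 30 mg/kg and 14 d 58% against 68.3%. The counts at 30 mg/kg were 144 at 14 d and 825 at 28 d with only the groups of the same control set. Without 1 array, the 14 d count was 252 and 486 without treated replicates 3 and 2 and 428 and 409 without control replicates 1 and 2. The 28 d count was 808 and 1184 without treated replicates 2 and 3 and 1385 without control replicate 3, and it rose to 2824 without treated replicate 1.

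The 14 d comparisons at 30 and 100 mg/kg share 3 control arrays. Their fold changes correlated across transcripts, which are not independent replicates, with r = 0.62, against 0.50 for simulated unchanged groups with the same controls. The covariance was 0.138, against 0.0197 simulated. They called 671 transcripts in the same direction, where independent lists would share 185. The simulation gave 0, but its unchanged groups are hardly ever called, so this 0 does not measure what shared controls add. With 3 controls no split left 2 in each part, so some of the excess can come from the shared controls.

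Piperonyl butoxide changed 428 transcripts at 14 d (276 raised, 152 lowered) and 2390 at 28 d (1107 raised, 1283 lowered). Of the 428, 94.4% had the same sign at 28 d and 285 were called in the same direction. The test of the difference between days passed for 9 transcripts, and for 0 with only the same control set. That count moved widely without 1 array: it was 450 and 101 without the 28 d treated replicates 2 and 3, 2 without the 14 d treated replicate 3, and 3 and 4 without control replicate 2 at 14 and at 28 d. Without the 28 d treated replicate 1 it was 6. At 28 d it called 448 transcripts in the same direction as methapyrilene at 30 mg/kg, with which it shares its 3 controls. Independent lists would share 111.6, and some of the excess can come from the shared controls. The simulation gave 0, but its unchanged groups are hardly ever called, so this 0 does not measure that part. The correlation across transcripts was 0.38, against 0.50 in the simulation, and the covariance 0.0429, against 0.0196. The 28 d split was 57.8% raised, against 46.3%, with arrays centred on their medians. The counts were 131 at 14 d and 873 at 28 d with only the same control set. The 14 d count was 197 and 245 without control replicates 2 and 3 and 277 and 262 without treated replicates 1 and 3. The 28 d count was 1057 without treated replicate 1 and 1525 without control replicate 2, and it rose to 3424 and 2813 without treated replicates 2 and 3.

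Cyproterone acetate changed more transcripts in the F than in the M groups, and its effects differed between them. It changed 2235 transcripts at 14 d and 2540 at 28 d in the M groups, and 3087 and 3406 in the F groups. Within a group type the days resembled each other: 95.8% of the 14 d calls in M and 97.2% in F had the same sign at 28 d, and the test of the difference between days passed for 2 transcripts in each, and for 0 in each with only the same control set. Without 1 array that count ran from 1 to 3 in M and from 1 to 5 in F, the 5 without the 28 d treated replicate 1. The effect in F minus the effect in M passed the test for 759 transcripts at 14 d and 779 at 28 d. The M calls were 52.5% rises at 14 d and 54.5% at 28 d, and 75.4% and 67.2% with arrays centred on their medians. For the F minus M difference, the share above 0 was 57.2% and 59.4%, and 45% and 43.4% with centring.

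The F and M controls differed strongly, and most transcripts chosen for a 2-fold difference in the controls differed less under cyproterone acetate. In controls, 1779 transcripts differed at 14 d and 1727 at 28 d, against 383 and 1432 in treated animals. At 14 d both directions fell, from 870 to 288 higher in F and from 909 to 95 higher in M. At 28 d those higher in M fell from 808 to 498, and from 147 to 61 at least 2-fold. Those higher in F at 28 d did not fall, with 919 in controls and 934 in treated animals, and 181 and 197 at least 2-fold. With arrays centred, 59.8% and 63.3% of the control calls were higher in F, against 48.9% and 53.2%, and 53.8% of the treated calls at 28 d, against 65.2%. The count in treated animals was 187 at 14 d without F replicate 3, and at 28 d 731 without F replicate 4 and 894 without M replicate 2. At least 2-fold differences in the 14 d controls defined 160 F-higher and 148 M-higher transcripts, which were then measured in the 28 d animals. The median F minus M difference of the F-higher set was 1.44 in controls and 0.42 in treated animals, smaller in 144 of 160. That of the M-higher set was -1.44 and -0.38, smaller in size in 141 of 148. Sets taken from the 28 d controls and measured at 14 d moved from 1.27 to 0.33, in 167 of 181, and from -1.57 to -0.37, in 134 of 147. The compound lowered 98 and raised 4 of the F-higher set in the F group and lowered 60 and raised 7 of the M-higher set in the M group at 28 d. It raised 55 and lowered 5 of the M-higher set in the F group, and each of these 3 shifts passed the test with an estimated correlation. In the M group it raised 34 and lowered 16 of the F-higher set (adjusted p = 0.00436, and 0.207 with an estimated correlation). ENSRNOT00000017310, M-higher by a difference of -8.69 (SE 0.32) in the 14 d controls, changed by -3.03 (SE 0.32) in the M group and by 1.18 (SE 0.32, adjusted p = 0.00492) in the F group at 14 d.

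**Figure D4:**
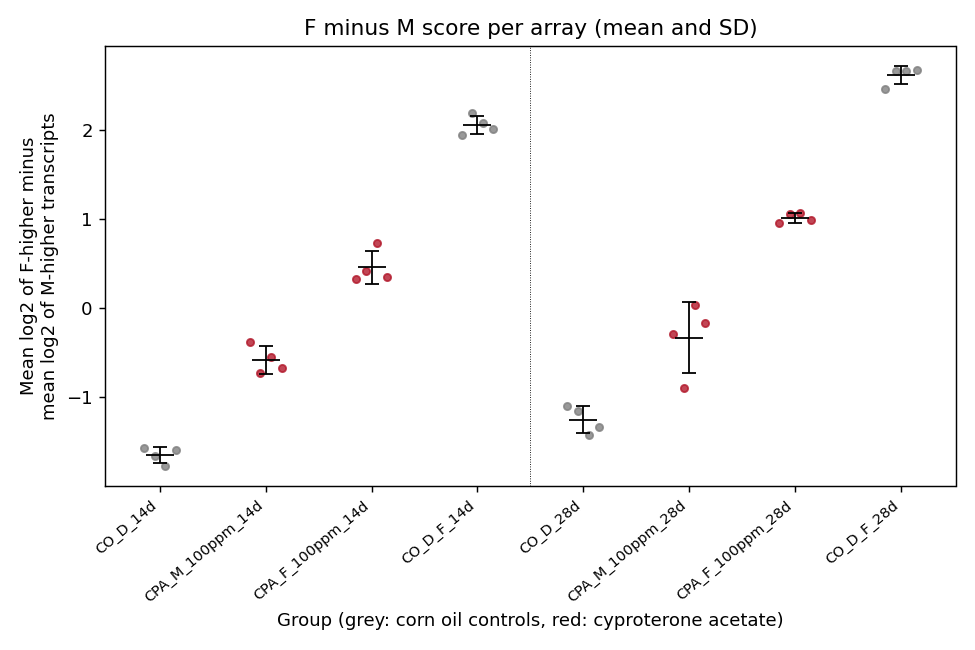
Mean log2 value of F-higher transcripts minus that of M-higher transcripts on each array (y axis) of the cyproterone acetate study (x axis: groups, at 14 d to the left and 28 d to the right of the dotted line). Grey points are corn oil controls, red points treated animals, and bars the mean and SD of 4 arrays. Each array is scored on sets from the controls of the other day. Arrays at 28 d use the 160 F-higher and 148 M-higher transcripts of the 14 d controls. Arrays at 14 d use the 181 and 147 of the 28 d controls. At 28 d the means are -1.26 and 2.62 in the M and F controls and -0.33 and 1.01 in the treated M and F groups.

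The M-higher set also fell in treated groups of other studies. Methapyrilene lowered 103 of the 148 at 100 mg/kg (median -1.22) and 63 at 30 mg/kg at 28 d (median -0.65). Wy-14643 lowered 79 and raised 16 (median -0.63), piperonyl butoxide at 28 d lowered 48 and raised 7 (median -0.48), and phenobarbital at 90 d lowered 28 and raised 5 (median -0.46). Pioglitazone at 63 mg/kg lowered 17 and raised 0 (median -0.22). All of these passed the test with an estimated correlation. That test was not passed for phenobarbital at 14 d, with 6 lowered and 3 raised (adjusted p = 0.015, and 0.299 with an estimated correlation), or at 28 d, with 8 and 6 (0.000469 and 0.133). The same holds for 1,4-dichlorobenzene, with 35 and 13 (2.32e-05 and 0.0663), rosiglitazone, with 7 and 0 (0.00154 and 0.173), and pioglitazone at 16 mg/kg, with 2 and 0 (0.000298 and 0.121). The M-higher set taken from the 28 d controls passed it for 1,4-dichlorobenzene, with 40 lowered and 12 raised (0.0194). The F-higher set rose with phenobarbital at 90 d, with 25 raised and 2 lowered (adjusted p = 0.000559 with an estimated correlation), and did not pass the test at 14 d (7 raised, 4 lowered, adjusted p = 0.844) or 28 d (8 raised, 5 lowered, adjusted p = 0.94). Methapyrilene at 30 mg/kg raised 33 and lowered 2 at 28 d (0.00298 with an estimated correlation), while Wy-14643 raised 49 and lowered 24 (0.205) and pioglitazone at 63 mg/kg raised 7 and lowered 7 (0.725). How far these shifts differ between compounds or times was not tested. With methapyrilene at 100 mg/kg, 63 rose and 33 fell (adjusted p = 0.0266, and 0.329 with an estimated correlation).

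Pioglitazone and rosiglitazone, thiazolidinediones and agonists of the nuclear receptor PPAR gamma, changed 11 to 542 transcripts. Pioglitazone at 63 mg/kg changed 542 (210 raised, 332 lowered), 9 of them at least 2-fold, and at 16 mg/kg 11. The 11 became 0 without control replicate 1 and without treated replicate 1, 2 and 6 without control replicates 2 and 3, 3 without treated replicate 2, and 18 without control replicate 5. Rosiglitazone at 10 mg/kg changed 153 (45 raised, 108 lowered), 16 of them at least 2-fold, and 426 with all arrays and 238 without dim transcripts. The compounds were given at different doses, so their structures cannot be compared at a matched dose. All 3 groups share 5 water controls, which alone push changes to the same sign. Of the 542 transcripts, 97.6% had the same sign with rosiglitazone, against 89.2% (86.2% to 92.1% in 100 draws) of the 542 most changed in simulated unchanged groups. With the controls split in 2, the median over 20 splits was 84.1% (79% to 87.8%) of the 542 most changed. Split comparisons share no controls, so the simulated 89.2% does not apply to that share. In the same direction 72 were called, where independent lists would share 2.02. The simulation gave 0, but its unchanged groups are hardly ever called, so this 0 decides nothing. With the controls split, the lists were shorter, with medians of 126.5 and 63 calls. They shared 1 to 12 (median 6.5), where independent lists of that length would share 0.153. The correlation of pioglitazone at 63 mg/kg with rosiglitazone across transcripts was 0.58, against 0.43 for simulated unchanged groups with the same controls. It was 0.26 on average with the controls split, with a range of 0.21 to 0.31, where the simulated value does not apply. The covariance was 0.0251, against 0.0118 simulated. The test of the difference passed for 1 transcript, which was lower with pioglitazone by a log2 difference of -1.59. The 95% interval of the difference had a median half-width of 0.30 and lay within 2-fold for 97.1% of transcripts. That count was 0 with only the same control set, 2 to 5 with centring, quantile normalization, all arrays, trend and robust variances or without dim transcripts, and 0 to 7 without 1 array, the 7 without rosiglitazone replicate 1. Between the doses of pioglitazone 3 transcripts differed, with 2814 at an unadjusted p under 0.05. The 3 became 29 with arrays centred, 14 without dim transcripts and 0 with only the same control set. Without 1 array the count ran from 1, without 63 mg/kg replicates 2 and 5, to 31, without 63 mg/kg replicate 3, and it was 15 and 10 without 16 mg/kg replicates 1 and 2. With quantile normalization, 41.2% of the rosiglitazone calls were rises, against 29.4%. With only the same control set the counts were 154, 0 and 5 for pioglitazone at 63 and 16 mg/kg and rosiglitazone. The pioglitazone 63 mg/kg count was 265 without treated replicate 2 and 282, 274 and 358 without control replicates 1, 2 and 5, and the rosiglitazone count was 49 and 24 without treated replicates 2 and 4.

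Transcripts shared by the carcinogens were counted at 28 d, with cyproterone acetate in the M group and methapyrilene at 30 mg/kg. Of 397 transcripts called in the same direction for at least 4 of the 6, and in no direction for either non-carcinogen, 242 rose and 155 fell. With only the groups of the same control set in each fit, 220 were shared in this way. Calls shuffled over transcripts gave at most 11 in 1000 shuffles, which leaves out that methapyrilene and piperonyl butoxide share controls. Without piperonyl butoxide, 161 were shared by at least 4 of 5. All 6 carcinogens shared 16. 1,4-Dichlorobenzene held 220 of the 242 raised transcripts (median log2 change 0.54), and phenobarbital 95 (median 0.26). Of the 155 lowered ones, phenobarbital held the fewest, 23 (median -0.18), and 1,4-dichlorobenzene held 110 (median -0.46). Methapyrilene at 30 mg/kg held 109 of the raised (median 0.32) and 111 of the lowered ones (median -0.58). Piperonyl butoxide held 207 and 148, Wy-14643 210 and 148, and cyproterone acetate in M 209 and 133. Other groups of the same compounds were not used in the choice, though their compounds were. Methapyrilene at 100 mg/kg raised 172 of the 242 and lowered 131 of the 155, where it raised 5582 and lowered 5227 of all 22470. Cyproterone acetate in the F group at 28 d raised 154 and lowered 73 (2003 and 1403 of all). Piperonyl butoxide at 14 d raised 77 and lowered 45 (276 and 152 of all). Methapyrilene at 30 mg/kg at 14 d raised 60 and lowered 53 (519 and 241). Phenobarbital at 14 d had the fewest among these groups, 51 raised and 7 lowered (151 and 172). Before the non-carcinogens were considered, 252 transcripts rose and 172 fell, and pioglitazone at 63 mg/kg moved 6 and 17 of these in the same direction and rosiglitazone 0 and 4. In the opposite direction they moved 1 and 3 of the 252 and 0 and 0 of the 172. Of all 22470 transcripts, pioglitazone at 63 mg/kg raised 210 and lowered 332 and rosiglitazone raised 45 and lowered 108. The medians of the 252 were -0.01 with pioglitazone and -0.02 with rosiglitazone, and those of the 172 were -0.13 and -0.07.

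The carcinogens changed 2356 transcripts on average at 28 d and the non-carcinogens 347.5. An exact two-sided permutation test over the 28 splits of the 8 compounds gave p = 0.143, where the smallest p it allows is 0.0714. Both non-carcinogens and no carcinogen were given in water in a set of their own, so class cannot be told apart from vehicle and set. Control groups of different sets differed from each other at 28 d: in 753 to 3789 transcripts between water and the controls of other sets, in 74, 796 and 992 between carboxymethylcellulose controls, in 718 between corn oil controls, and in 174 between the corn oil controls of cyproterone acetate and the carboxymethylcellulose controls of phenobarbital. The corn oil and carboxymethylcellulose controls that share a set letter differed in 131.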

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

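The tests of the scaling between arrays, of swapped arrays, of an effect on transcripts that differ between F and M, and of mixing fractions, 1 for all arrays or 1 for each, were chosen only after the result was seen, as were the counts of other splits and the sets and scores used here.

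Methapyrilene at 100 mg/kg differed from 30 mg/kg in 8157 transcripts. Most of these calls were kept under other scalings between arrays, 77.6% with quantile normalization and 7095 of 8157 with arrays centred on their medians. The balance of directions was not kept with centring, where 40.1% of the calls were rises, against 57.4%. Scaling as the source of most of the calls is thus argued against. As a source of part of them, and of the balance of rises and falls, scaling stays open. A single array is argued against by the counts without 1 array, the lowest of which is 6841. A larger form of the response at 30 mg/kg may account for part of it, since 95.5% of the calls at 30 mg/kg and 28 d, with other control animals, had the same sign at 100 mg/kg. Other cell types in the liver were not tested, because no marker could be named, so they stay open.

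Under cyproterone acetate the F and M groups came closer to each other over the transcripts at least 2-fold apart in their controls. The number called higher in F at 28 d did not fall, with 919 in controls and 934 in treated animals. The effect of the compound differed between the groups in 759 transcripts at 14 d and 779 at 28 d. Swapped arrays are argued against, since 0 treated arrays had an F minus M score beyond the opposite treated group, and so is a narrower scale, with a ratio of SDs of 1.003. Mixed RNA as the whole of the pattern is argued against by the levels at 28 d of 83 transcripts at least 4-fold apart in the 14 d controls: 2.41% kept 90% of their difference, as few as mixing would leave, but with the best fraction for each treated array at least 21.7% lay more than 2-fold and 2 SD from the level it gives, against at most 4.82% in control arrays. The best single fraction, 23%, allows a log2 difference of at most 1.74, which 20 of the 83 exceeded by more than 2 SE, while 16 had under 10% of their control difference left. The change of transcripts that differ between F and M controls was measured against the controls of each group. At 28 d, of the sets from the 14 d controls, the compound lowered 98 and raised 4 F-higher transcripts in the F group. In the M group it lowered 60 and raised 7 M-higher ones. Lowered members of a group's own set thus outnumbered raised ones at least 8.57 to 1, which only restates the pattern. How the compound brings it about was not tested and stays open.

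Replicate 1 of piperonyl butoxide at 28 d lay farther from its group than any other of the 112 arrays, at a root mean square of 0.51. Its deviation from the other 2 arrays had a correlation of 0.037 with the 14 d effect across transcripts, so a noisy array may account for it. A stronger response of that animal is argued against by its slope on the 14 d effect, 0.873 times the highest of the other 2. A wrong label cannot be told apart, because its correlation with its own group exceeded the highest with another, 1,4-dichlorobenzene, by only 0.03. Without it 1057 transcripts were called in place of 2390. Without replicate 2 or 3 of the same group the count rose, to 3424 and 2813, so the 2390 depends strongly on which arrays are used.

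Some arrays stood apart in groups of 4 or 5. Of 126 groups of values tested, 15 held such an array, where chance gives about 1 in 20: 1 for distance, 2 for set scores and 12 for the printed transcripts. Replicate 4 of cyproterone acetate M at 28 d lay nearer to its group mean (0.28) than the others (0.30). Replicate 1 of the F controls at 28 d had an F minus M score of 2.46, against 2.66 to 2.67 in the others. Replicate 1 of 1,4-dichlorobenzene had a phenobarbital set score of 0.96, against 1.13 to 1.16.

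ENSRNOT00000013729 stood apart at 8.11 in replicate 5 of the corn oil controls of 1,4-dichlorobenzene, against 1.53 to 2.41 in the others. It stood apart at 3.34 in replicate 5 of the 14 d phenobarbital controls, 3.66 in replicate 2 of the 28 d M controls of cyproterone acetate, 3.93 in replicate 4 of cyproterone acetate F at 28 d and 3.20 in replicate 3 of the water controls. ENSRNOT00000044127 was at 3.91 in replicate 4 of the 90 d phenobarbital controls. ENSRNOT00000052369 was at 4.09 in replicate 4 of the 28 d phenobarbital controls, 2.24 in replicate 2 of the Wy-14643 controls, 3.42 in replicate 3 of cyproterone acetate F at 14 d, 4.22 in replicate 2 of cyproterone acetate M at 14 d, 2.50 in replicate 1 of 1,4-dichlorobenzene and 4.38 in replicate 5 of phenobarbital at 28 d.

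A test of the difference of the effect between days passed in 16 transcripts for phenobarbital (28 against 14 d), 1 for phenobarbital (90 against 28 d), 2 for cyproterone acetate in M, 2 in F and 9 for piperonyl butoxide. With only the same control set these counts were 1, 0, 0, 0 and 0, and without 1 array they ran from 3 to 69, 0 to 8, 1 to 3, 1 to 5 and 2 to 450. Chance cannot be excluded for phenobarbital 90 against 28 d, where 11 of 100 splits gave as many (highest other 6), for cyproterone acetate in F (14 of 100, 8) or for piperonyl butoxide (21 of 100, 404). For phenobarbital 28 against 14 d (3 of 100, 39) and cyproterone acetate in M (1 of 100, 1) the share of splits alone does not settle it.

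Of the 8 treated arrays left out for quality, 6 had a phenobarbital set score above all used control arrays of their comparison. It was 1.16 in replicate 4 of 1,4-dichlorobenzene, against at most 0.08 in controls. It was 0.90 and 0.84 in replicates 2 and 4 of phenobarbital at 14 d (controls at most 0.11, used treated arrays at least 0.95), and 1.43 and 1.45 in replicates 1 and 3 at 90 d (controls at most 0.07). Replicate 5 of rosiglitazone had 0.13, against at most 0.08 in controls and in the used arrays of its group.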

How the results depend on the processing

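The draws of 3 arrays per group, the F against M comparisons and all tests of transcript sets were added after the data were examined. Over all alternatives, 188 counts moved by more than 1.5 times and 666 did not; of 100 shifts of 7 sets, followed under 8 alternatives, 43 values fell below the threshold (30 of them with an estimated correlation), 4 rose past it and 753 kept side and direction, as did all 143 values of printed transcripts. No set shift or printed transcript reversed its direction. The mean over the probe sets of a gene and the 29 gene lists were not run, because no probe set could be paired with a gene. Low signal was not separable from absence, since the files give no detection calls. The causes of the changes below were not tested.

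With all arrays, phenobarbital called 1085 at 14 d and 896 at 90 d, rosiglitazone 426, phenobarbital 28 minus 14 d 66 and pioglitazone minus rosiglitazone 4. With only the same control set, phenobarbital called 85, 148 and 280 at 14, 28 and 90 d, methapyrilene 30 mg/kg 144 and 825 and piperonyl butoxide 131 and 873 at 14 and 28 d, pioglitazone 0 and 154 at 16 and 63 mg/kg, and rosiglitazone 5. Phenobarbital 28 minus 14 d then gave 1, and 0 were left for phenobarbital 90 minus 28 d, cyproterone acetate 28 minus 14 d in M and in F, piperonyl butoxide 28 minus 14 d and both pioglitazone differences. The carcinogens shared 220 in that fit, 1139 for at least 3, 119 for at least 5, and 161 without piperonyl butoxide.

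Pioglitazone 63 minus 16 mg/kg gave 29 with centring and 14 without dim transcripts, and pioglitazone minus rosiglitazone 2 with centring, 4 with quantile normalization and 5 both without dim transcripts and with trend and robust variances. Without dim transcripts, rosiglitazone gave 238, phenobarbital 90 minus 28 d 5, cyproterone acetate 28 minus 14 d 1 in M and 1 in F, and piperonyl butoxide 28 minus 14 d 5. Cyproterone acetate F 28 minus 14 d gave 1 with trend and robust variances.

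Same-numbered arrays did not pair: over 60 pairs the correlation of deviations ran from -0.114 to 0.0757, and 10 of 60 correlated best with their own number. With the replicate block, phenobarbital called 96 at 14 d and 223 at 90 d, 1,4-dichlorobenzene 833 and pioglitazone 16 mg/kg 6. The block gave 2 for phenobarbital 28 minus 14 d, 0 for 90 minus 28 d and 9 for pioglitazone 63 minus 16 mg/kg. F minus M gave 458 and 378 in controls and 66 and 292 in treated animals at 14 and 28 d with the block.

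With 3 arrays per group, phenobarbital called 136 and 104 at 14 and 28 d, 1,4-dichlorobenzene 755, cyproterone acetate M 1436 and 1643, pioglitazone 6 and 74 at 16 and 63 mg/kg and rosiglitazone 62. The phenobarbital-raised set in rosiglitazone had a median of -0.0629 (adjusted p = 0.133) with all arrays, -0.0514 (0.115) with quantile normalization, -0.0543 (0.109) without dim transcripts and -0.0854 (0.35) with an estimated correlation. With an estimated correlation its median was 0.27 (adjusted p = 0.158) in Wy-14643 and 0.0748 (0.173) in methapyrilene 30 mg/kg at 28 d, and that of the F-higher set in cyproterone acetate M at 28 d 0.16 (0.207).

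Without 1 array, counts ran from 138 to 400, 191 to 275 and 241 to 384 for phenobarbital at 14, 28 and 90 d, 4930 to 5312 for Wy-14643 and 953 to 1302 for 1,4-dichlorobenzene. Cyproterone acetate gave 1560 to 2136 and 1717 to 2481 in M and 2405 to 2730 and 2685 to 3157 in F at 14 and 28 d. Methapyrilene gave 252 to 702 and 808 to 2824 at 30 mg/kg and 9508 to 9770 at 100 mg/kg, piperonyl butoxide 197 to 302 and 1057 to 3424. Pioglitazone gave 0 to 18 and 265 to 584, rosiglitazone 24 to 170. For differences, phenobarbital gave 3 to 69 (28 minus 14 d) and 0 to 8 (90 minus 28 d), cyproterone acetate F minus M 579 to 778 and 532 to 800, its 28 minus 14 d 1 to 3 in M and 1 to 5 in F. Methapyrilene gave 0 to 15 (days) and 6841 to 8141 (doses), piperonyl butoxide 2 to 450, the last without its 28 d replicate 2, and pioglitazone 1 to 31 (doses) and 0 to 7 (against rosiglitazone). F minus M gave 1332 to 1559 and 1311 to 1647 in controls and 187 to 424 and 731 to 1503 in treated animals.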

Other observations

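The tests of sets, the counts of other splits and the comparisons of arrays and control groups in this part were chosen only after the result was seen, while the counts with only the same control set and without 1 array had been planned.

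The 182 transcripts that methapyrilene at 30 mg/kg lowered at both days fell in other studies as well. Wy-14643 lowered 132 of them and raised 15 (median -0.57, adjusted p = 0.000207 with an estimated correlation), and cyproterone acetate in the M group at 28 d lowered 72 and raised 5 (median -0.21, adjusted p = 0.0027 with an estimated correlation). Pioglitazone at 63 mg/kg lowered 21 and raised 2 (median -0.10, adjusted p = 5.24e-10, and 0.0613 with an estimated correlation). Of the 397 that it raised at both days, Wy-14643 raised 208 and lowered 14 (adjusted p = 0.0221 with an estimated correlation), and cyproterone acetate in the F group at 28 d raised 192 and lowered 10 (adjusted p = 0.0135 with an estimated correlation). Cyproterone acetate raised 132 and lowered 14 in the F group at 14 d (adjusted p = 3.39e-15, and 0.0563 with an estimated correlation). In the M group it raised 46 and lowered 27 at 14 d (0.0195 and 0.587) and 90 and 14 at 28 d (1.2e-06 and 0.25), and 1,4-dichlorobenzene raised 76 and lowered 5 (3.86e-15 and 0.0563). Of the 182 lowered ones, cyproterone acetate in the F group lowered 43 and raised 25 at 14 d (0.0156 and 0.482) and 63 and 18 at 28 d (5.2e-07 and 0.133). Whether these shifts differ between compounds was not tested.

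The low cluster of ENSRNOT00000052369 held arrays of many groups. All 5 arrays of 1,4-dichlorobenzene, the unused one included, lay in it, and so did 2 of 3 with methapyrilene at 100 mg/kg, 2 of 3 with piperonyl butoxide at 14 d, 2 of 5 with Wy-14643, 2 of 5 with pioglitazone at 63 mg/kg and 2 of 5 with rosiglitazone. Over the series it held 20 of 70 treated and 3 of 53 control arrays.

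The technical repeat of a 14 d control animal differed from its first array with an SD of 0.18 log2 units across transcripts. Other pairs of that group differed with 0.32 to 0.37, and the closest pair within any group with 0.28. Arrays marked as not of good quality lay 0.27 to 0.35 from their group means, with a median of 0.31, against a median of 0.28 and a range of 0.25 to 0.51 for the others.

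Control groups of 1 vehicle and set changed with time in places: 635 transcripts differed between 90 and 14 d in the carboxymethylcellulose controls of phenobarbital, and 38 between 28 and 14 d. Between the 28 d and 14 d corn oil controls, limma called 2 in the M groups and 0 in the F groups.

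Other splits of the same arrays were counted for each comparison. The shares were not adjusted for the number of comparisons, so each statement holds for its comparison taken alone. Chance can be excluded, at a share of splits under 0.05, where only the real split, 1 of 100 drawn, gave as many transcripts: phenobarbital at 28 d (277, highest other 152), Wy-14643 (5466, 3152) and pioglitazone at 63 mg/kg (542, 97). The same holds for 1 of 35 splits with phenobarbital at 90 d (446, 176), 1,4-dichlorobenzene (1340, 48), and cyproterone acetate in M (2235, 104, and 2540, 238) and F (3087, 416, and 3406, 703) at 14 and 28 d. It holds for 1 of 56 with rosiglitazone (153, 49). For phenobarbital at 14 d (323), 2 of 56 splits gave as many, a share under 0.05. There the split that set control replicates 3, 4 and 5 against the other arrays gave 461, more than the real one. The real count was 85 with only the same control set and 138 without phenobarbital replicate 5. For phenobarbital at 14 d the share alone therefore does not settle the question of chance. Pioglitazone at 16 mg/kg reached its 11 transcripts in 3 of 56 splits, with a highest other of 21, so chance cannot be excluded.

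With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave the highest count in each case. The counts were 760 (highest other 0) and 2120 (489) for methapyrilene at 30 mg/kg at 14 and 28 d, 10809 (14) at 100 mg/kg, 428 (1) and 2390 (614) for piperonyl butoxide at 14 and 28 d, and 8157 (199) between the doses of methapyrilene.

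For differences between comparisons, chance can be excluded for cyproterone acetate F minus M at 14 d (759, 1 of 100, highest other 178) and 28 d (779, 1 of 100, 293). The share of splits is also under 0.05 for its 28 minus 14 d in M (2, 1 of 100, highest other 1) and for phenobarbital 28 minus 14 d (16, 3 of 100, 39). The share alone does not settle the question of chance for either. For phenobarbital another split gave more than the real one, and both counts are small and depend on the setting. With only the same control set they were 0 and 1, and without 1 array they ran from 1 to 3 and from 3, without the 14 d control replicate 4, to 69, without the 14 d control replicate 1. Chance cannot be excluded for phenobarbital 90 minus 28 d (1, 11 of 100, 6), cyproterone acetate F 28 minus 14 d (2, 14 of 100, 8), piperonyl butoxide 28 minus 14 d (9, 21 of 100, 404), pioglitazone 63 minus 16 mg/kg (3, 26 of 56, 24) or pioglitazone minus rosiglitazone (1, 35 of 56, 16). For methapyrilene 30 mg/kg 28 minus 14 d the real count is 0, which all 100 of 100 splits reach by design (highest other 11), so the splits say nothing. For piperonyl butoxide the 404 of another split is several times the real count, and the reason was not tested. For F minus M, 1 of 35 splits gave as many in the 14 d (1779, highest other 143) and 28 d (1727, 220) controls and in the 14 d (383, 96) and 28 d (1432, 483) treated animals. Chance can be excluded for these F minus M counts. The 397 transcripts shared by carcinogens were reached in 1 of 100 sets of splits, with a highest other of 0. Those splits mix treated with control arrays and so take away the effect of every compound. They therefore cannot tell whether the sharing exceeds that of compounds with unrelated effects.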
